A study of Mus musculus with 4 samples.

How the data were processed

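RNA was measured by sequencing in cultured primary mouse pancreatic ductal cells from 4 animals. The labels put 2 libraries in the control group (Hhex floxed alleles without Cre) and 2 in the Hhex knockout group (floxed alleles with a tamoxifen-inducible Cre driven by the Sox9 promoter). Both groups were treated in culture with 500 nM 4-hydroxytamoxifen, the compound that activates the Cre, for 4 days. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq RNA v2 kit from total RNA.

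The authors deposited a table of raw counts and a table of RPKM values, both with 1 line per RefSeq transcript. Per the submitters' processing notes, the genome was mm9 and edgeR was used, with no version stated. The aligner, the counting program and its treatment of strand were not given in the sources used here. The deposited counts are whole numbers and were not normalized. By the definition of the unit, the deposited RPKM values are the authors' counts scaled by transcript length and by a library total. That total was estimated here from the ratio of counts to RPKM. The tables hold 28644 transcripts of 22869 gene symbols, of which 3705 symbols have several transcripts. Transcripts of 1 gene often had near-equal counts. Of 1592 symbols with 2 transcripts and over 100 counts in control replicate 1, 20.48% had identical counts for both and 78.27% differed by less than 10%. Several transcripts of 1 gene are therefore not independent tests. Symbols are used as deposited, so that Fam5c, Lass3 and Wisp2 are older names.

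The total of the deposited counts was 25513289 in control replicate 1, 25257778 in control replicate 2, 39582625 in Hhex knockout replicate 1 and 30835777 in Hhex knockout replicate 2. With 1 transcript per gene the totals were 18842439, 18638815, 29137636 and 22750300. Intervals of CPM are 95% intervals of the count in a single library, so they cover counting error only and not the spread between animals. They treat each count as independent, although reads carried no molecular identifiers to show this.

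Counts were tested with R 4.3.3 and edgeR 4.0.16. Transcripts were kept by filterByExpr (minimum count 10, minimum total count 15), scaled with TMM factors and tested with the quasi-likelihood F test, knockout minus control, with Benjamini-Hochberg adjustment over the 20949 transcripts tested and a threshold of 0.05. The other 7695 transcripts were not tested. Levels are given as CPM of the TMM-scaled library, and fold changes with 95% intervals. For olfactory, vomeronasal and trace amine receptor genes, CPM was instead taken over the unscaled total of the transcripts that stand for a gene. Where a symbol has several transcripts, the one with the highest mean count stands for the gene. The common biological coefficient of variation was 0.2339, with 2 residual and 5.359 prior degrees of freedom. In counts simulated from the means and library sizes of this comparison (20949 transcripts, 100 changed per fold size), 97% of 4-fold changes and 26% of 2-fold changes were recovered, and 9 unchanged transcripts were called. The simulation drew transcripts independently, all with the common coefficient of variation. It therefore does not measure recovery for transcripts that vary more between libraries or share reads.

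For the comparison of knockout with control, 36 gene lists fixed before the data were examined were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. With the preset correlation, camera's p rests on the spread over genes and not over animals. With an estimated correlation it rests on 2 residual degrees of freedom. The lowest adjusted p of any list was then 0.8616, so a miss there does not tell lists apart. Sex-linked and globin genes were listed as checks with values only. Named genes were Hhex, Sox9 and Npr3, then in each direction up to 10 called genes with the largest fold change, a mean CPM of at least 5 and no overlap between groups. From each list past the threshold, or with at least 3 called members, up to 4 members with the smallest p were named, plus the called member with the smallest p going the other way, and from other lists up to 2. Where fewer than 10 genes pass in a direction, those with the smallest p fill it to 5 as values. Genes named outside this rule are marked as chosen after their values were seen.

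The alternatives were other scaling factors, filters, tests and thresholds, counts summed per symbol, limma-trend on the authors' deposited RPKM, DESeq2 1.42.0, and each library left out. Alternatives added after the data were seen were 1 transcript per gene, no X and Y genes, and the share of reads in transcripts as a covariate. Chromosomes and gene order came from a RefSeq table of assembly GRCm38, and exon lengths from GENCODE release M21 of the same assembly, so no coordinates are given. No sample was left out.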

Results

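Gene expression was compared between primary pancreatic ductal cells labelled Hhex knockout (n = 2) and cells labelled control (n = 2). The question of the design is which transcripts in ductal cells depend on Hhex, a homeobox transcription factor of the developing liver and pancreas. By the labels only the knockout group carried the Cre, and no group carried the Cre without the floxed alleles. Effects of the Cre itself therefore cannot be told apart from loss of Hhex, including for Sox9, whose promoter drives the Cre. Each library held between 25257778 and 39582625 counts over the transcripts.

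The targeted gene was not lower in the libraries labelled knockout. Hhex (NM_008245) stood at 24.8 and 17.7 CPM in the controls and at 23.6 and 39.0 CPM in the libraries labelled knockout, a log2 fold change of 0.55 ± 0.27 (SE) with an edgeR adjusted p of 0.734. The label is therefore not borne out by the Hhex count, and the group is called "the libraries labelled knockout" throughout. The deleted part of the gene is not stated in the labels, and reads outside it would still be counted. Without Hhex knockout replicate 1 the Hhex log2 fold change was 0.84 (edgeR adjusted p = 1.455e-05), where a single library stands for the group.

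Sox9, a ductal transcription factor whose promoter drives the Cre, stood at 18.0 and 21.4 CPM in the controls and at 52.3 and 44.3 CPM in the libraries labelled knockout. Its log2 fold change of 1.30 ± 0.17 (SE) missed the threshold in edgeR (adjusted p = 0.0512). Sox9 passed with the edgeR exact test (adjusted p = 3.318e-06), with edgeR's robust quasi-likelihood fit (0.0275), without X and Y genes (0.0482), with DESeq2 (5.8e-06) and with limma-trend on log2(RPKM + 1) (0.0025). Sox9 missed in the other alternatives that kept every library and the 0.05 threshold without a fold limit. Its adjusted p there ran from 0.0518 with limma-trend on log2(RPKM + 0.1) to 0.235 in edgeR with the share of reads in transcripts as a covariate. It was 0.0975 in edgeR with counts summed per symbol. With each library left out in turn, so that a single library stands for 1 group, its log2 fold change lay between 1.15 and 1.46. Npr3, the clearance receptor for natriuretic peptides, stood at 20.1 and 33.1 CPM in the controls and at 47.7 and 198.6 CPM in the libraries labelled knockout, with an edgeR adjusted p of 0.344.

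**Figure D1:**
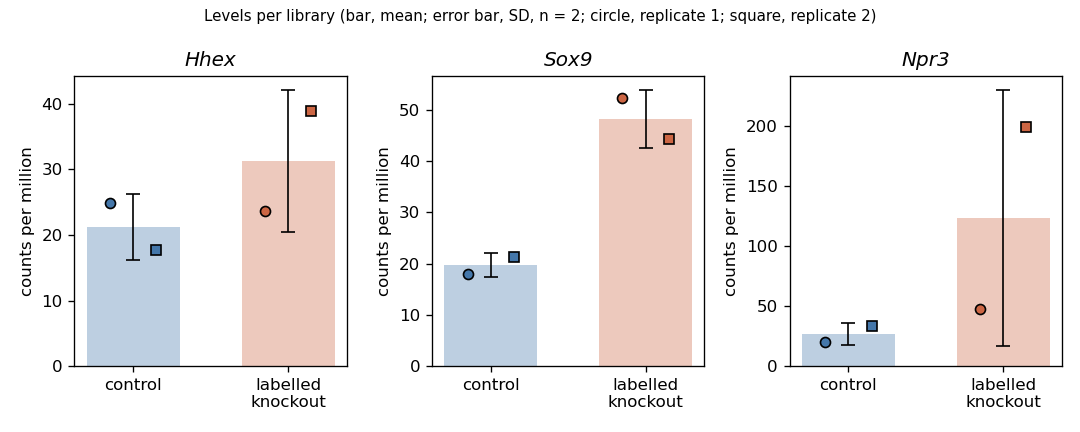
Levels of Hhex, Sox9 and Npr3 in CPM (counts scaled to the library size) for each library, with bars at the group mean and error bars of 1 SD (n = 2 per group). Hhex overlapped between groups, whereas both libraries labelled knockout lay above both controls for Sox9 and Npr3, neither of which passed the edgeR threshold.

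Cells labelled knockout had lost most transcripts of a coagulation inhibitor and of a membrane protein of the tetraspanin-like L6 family. Tfpi, which encodes tissue factor pathway inhibitor, fell from 94.7 ± 18.7 CPM (SD, n = 2) in the controls to 6.38 ± 0.464 CPM (SD, n = 2), a 14.9-fold decrease (edgeR adjusted p = 0.0011). Tm4sf1, an L6 family surface protein, fell 8.68-fold, from 154 to 17.7 CPM (edgeR adjusted p = 0.0018). Tm4sf4, a relative of Tm4sf1 listed among the ductal markers, fell 3.23-fold from 96.6 to 29.98 CPM (edgeR adjusted p = 0.0359).

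Another 5 genes passed the threshold downward. The interferon-inducible guanylate-binding protein genes Gbp8 and Gbp9 fell 4.82-fold and 3.20-fold, and both had an edgeR adjusted p of 0.0249. Slfn2, a Schlafen family gene of immune cells, fell 3.83-fold from 109 to 28.4 CPM (edgeR adjusted p = 0.0496). Il23a, which encodes a subunit of interleukin 23, fell 2.95-fold (edgeR adjusted p = 0.0452). Gpr161, an orphan receptor of the primary cilium that restrains Hedgehog signalling, fell 3.82-fold (edgeR adjusted p = 0.0284).

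Among the higher genes, Fam5c showed the largest fold change. Fam5c rose from 1.07 to 18.9 CPM, 17.6-fold with a 95% interval of 9.47 to 32.7 (edgeR adjusted p = 0.0249). Tnik, a kinase of the Wnt pathway, rose 8.24-fold from 5.32 to 43.6 CPM. Scel, which encodes the epithelial envelope protein sciellin, rose 6.10-fold from 3.97 to 24.1 CPM. Cd200, a surface ligand that restrains myeloid cells, rose 4.48-fold from 2.15 to 9.71 CPM (edgeR adjusted p = 0.0496).

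Klra4, Klra12, Klra15, Klra18, Klra22 and Klra33 also rose, by 3.64-fold to 3.79-fold. They belong to the Ly49 receptor family, which natural killer cells carry. Klra18 stood at 30.7 ± 7.36 CPM (SD, n = 2) in the controls and at 116 ± 6.67 CPM (SD, n = 2) in the libraries labelled knockout. They are members of a multigene family, and their ratios to Klra4 stayed within 1.17-fold across libraries, so their 6 calls are uncertain as separate genes. Summed over 10 natural killer and T cell genes, CPM was 3.86 and 2.59 in the controls and 1.23 and 3.26 in the libraries labelled knockout.

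Of the remaining 5 higher symbols, 4 fell outside the naming rule and were chosen after their values were seen. They were Porcn, the acyltransferase that lipid-modifies Wnt proteins, Sult1a1, a phenol sulfotransferase, Lass3, a ceramide synthase, and Sema3c, a secreted semaphorin. Their log2 fold changes lay between 1.51 for Sema3c and 1.83 for Sult1a1. The tuft cell kinase gene Dclk1 was called on 2 of its transcripts (log2 fold change 1.77, edgeR adjusted p = 0.0262), while its most abundant transcript had a log2 fold change of 1.99 and an edgeR adjusted p of 0.0686.

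**Figure D2:**
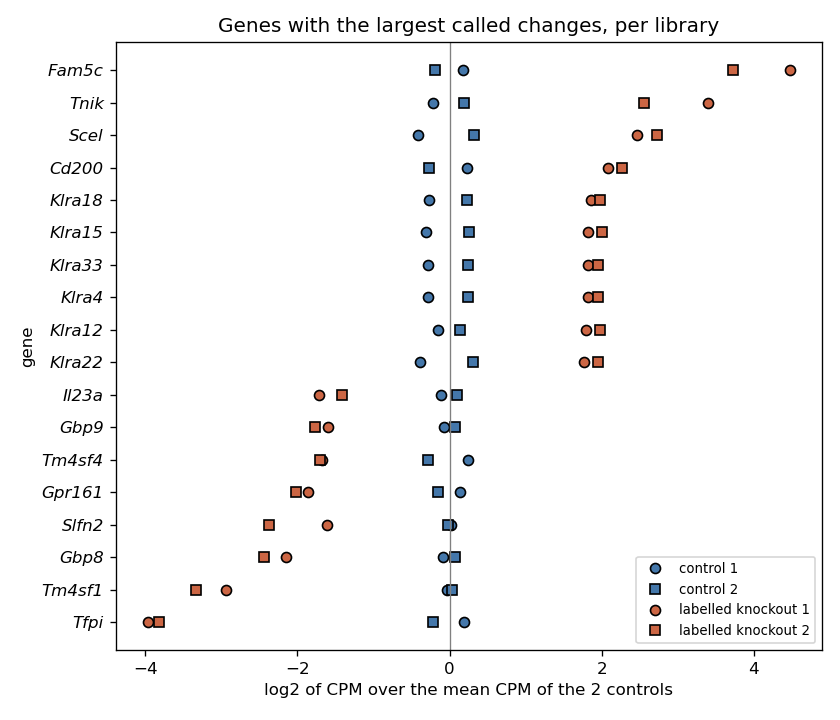
Each point is 1 library's log2 CPM relative to the mean of the 2 controls, for the genes with the largest called fold changes. The genes were selected for no overlap between groups, and run from Tfpi, 14.9-fold lower, at the bottom to Fam5c, 17.6-fold higher, at the top.

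In all, 32 of the 20949 transcripts tested passed an edgeR adjusted p of 0.05, 22 higher and 10 lower, which came to 15 higher and 8 lower symbols. With library totals or with upper-quartile factors in place of TMM, 0 transcripts were higher and 5 lower. With 1 transcript per gene, an alternative added after the data were seen, 0 were higher and 2 lower. No higher call therefore held once transcripts that share reads were reduced to 1 per gene. The 2 lower genes Tfpi and Tm4sf1 were called under all 17 alternatives that kept every library and the 0.05 threshold without a fold limit, and were the only 2 of the 23 symbols to be so. Without control replicate 1 no transcript was called by edgeR although 517 had an unadjusted p under 0.05, without control replicate 2 there were 3, without Hhex knockout replicate 1 there were 1742 and without Hhex knockout replicate 2 there were 1911.

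Ductal identity genes moved in both directions. Of the 22 ductal markers tested, edgeR called 1, Tm4sf4, and when adjusted over the list alone 3 rose and 4 fell. The 3 that rose were Sox9, Pkhd1, which encodes the ciliary protein fibrocystin, and the tetraspanin Tspan8, with log2 fold changes of 1.30, 0.54 and 0.69. The 4 that fell were Tm4sf4, the chloride channel gene Cftr, the mucin gene Muc1 and Ambp, with log2 fold changes of -1.69, -0.94, -2.24 and -1.88. Tspan8, Muc1 and Ambp were named here after their values were seen. As a list they had a camera adjusted p (limma) of 0.858, and fry's adjusted p for change in either direction was 0.0369.

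Matrix remodelling genes were also divided. Of 22 tested, edgeR called none over all genes, and adjusted over the list alone 3 rose and 2 fell. Plau, the urokinase gene, rose from 208 to 376 CPM and the collagenase gene Mmp13 fell from 2.17 to 0.625 CPM. Timp3 and Lamb3, chosen after their values were seen, had log2 fold changes of 1.08 and 0.71, and Plat, the tissue plasminogen activator gene, of -1.21. Camera (limma) gave an adjusted p of 0.178, and fry's for change in either direction was 0.0459.

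The list of NRF2 and xenobiotic response genes, which act in detoxification, passed camera upward (limma adjusted p = 0.0054) but missed the threshold at an adjusted p = 0.862 with an estimated correlation. No list passed with that estimate, so this miss, like those of the lists below, does not tell 1 list from another. Of the 16 members tested, 14 had positive fold changes, none passed edgeR over all genes, and adjusted over the list alone 6 rose and 1 fell. Aldh1a1, a retinaldehyde dehydrogenase, rose from 131 to 349 CPM, Gclc, the catalytic enzyme of glutathione synthesis, from 270 to 621 CPM and Gsr, the glutathione reductase, from 102 to 158 CPM. Gsta4, a glutathione transferase, fell from 122 to 66.7 CPM. Without Hhex knockout replicate 1, which had the larger mean shift of 0.56 against 0.21, the camera adjusted p was 0.417.

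The cell cycle list passed camera upward (limma adjusted p = 3.13e-06) but missed the threshold at an adjusted p = 0.862 with an estimated correlation. That estimate was 0.588, against the preset 0.01. Of 41 genes tested, 37 had positive log2 fold changes with a mean of 0.28, and none was called by edgeR over all genes or adjusted over the list alone. Ccnb2, a mitotic cyclin gene, stood at 7.85 and 14.7 CPM in the control and labelled-knockout means, and the topoisomerase gene Top2a at 93.4 and 125 CPM. The mean shift was 0.11 in Hhex knockout replicate 1 and 0.44 in replicate 2, and without replicate 2 the camera adjusted p was 0.0809.

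The list of unfolded protein response genes passed camera upward (limma adjusted p = 0.0015) but missed the threshold at an adjusted p = 0.862 with an estimated correlation. Of 23 tested, 20 had positive fold changes with a mean log2 fold change of 0.24, and 0 were called by edgeR over all genes or adjusted over the list alone. Herpud1, a factor of endoplasmic reticulum degradation, stood at 78.2 and 109 CPM, and Asns, the asparagine synthetase gene, at 169 and 264 CPM. Without control replicate 1 the camera adjusted p was 0.206.

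The list of cytokines, chemokines and NF-kB targets passed camera downward (limma adjusted p = 0.0054) but missed the threshold at an adjusted p = 0.862 with an estimated correlation. Of 29 genes tested, 22 had negative fold changes. Il23a was called by edgeR over all genes, and adjusted over the list alone 3 fell, Il23a, Tnf and Nfkbia, and 1 rose, the alarmin gene Il33. Nfkbia, the NF-kB inhibitor gene, fell from 243 to 133 CPM, and Il33 rose from 9.39 to 19.6 CPM. Without control replicate 2 the camera adjusted p was 0.222.

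For interferon response genes the list passed camera downward (limma adjusted p = 0.00043) but missed the threshold at an adjusted p = 0.862 with an estimated correlation. That estimate was 0.541, against the preset 0.01. Of 28 tested, 23 had negative fold changes, none passed edgeR over all genes, and adjusted over the list alone 2 fell, the antiviral genes Oas1g and Mx1. Both were lower in each library labelled knockout, with Oas1g at 3.90 and 4.50 CPM in the controls against 1.13 and 0.323 CPM, and Mx1 at 4.66 and 7.91 CPM against 2.38 and 1.61 CPM. The summed level of the list was 706 and 784 CPM in the controls, 770 CPM in Hhex knockout replicate 1 and 324 CPM in replicate 2. Hhex knockout replicate 2 was also the only female library by its Xist and Y-linked counts. The camera adjusted p was 0.965 without Hhex knockout replicate 2 and 0.106 without control replicate 2. Bst2, the antiviral tetherin gene, stood at 220 and 234 CPM in the controls and at 154 and 73.9 CPM in the libraries labelled knockout.

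Hepatocyte genes, as a list, passed camera downward (limma adjusted p = 0.0174) but missed the threshold at an adjusted p = 0.862 with an estimated correlation. All 7 tested had negative fold changes, and adjusted over the list alone 1 fell, Apob, from 5.08 to 1.06 CPM. Trf, the transferrin gene, stood at 79.1, 53.7 and 51.8 CPM and at 2.65 CPM in Hhex knockout replicate 2. Ttr and Tat were near the floor, with control means of at most 0.893 CPM. The camera adjusted p was 0.129 without control replicate 1, where the mean log2 fold change went from -1.14 to -0.47, and 0.0973 with library totals. In control replicate 1 the acinar, endocrine, endothelial and lymphocyte lists also lay 0.40 to 0.64 above the control mean in log2 CPM. Genes of olfactory and related receptors stood there at 301 CPM against 135 to 186 CPM in the other libraries. For these receptors CPM was taken over the unscaled total of the transcripts that stand for a gene, not over the TMM-scaled library.

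**Figure D3:**
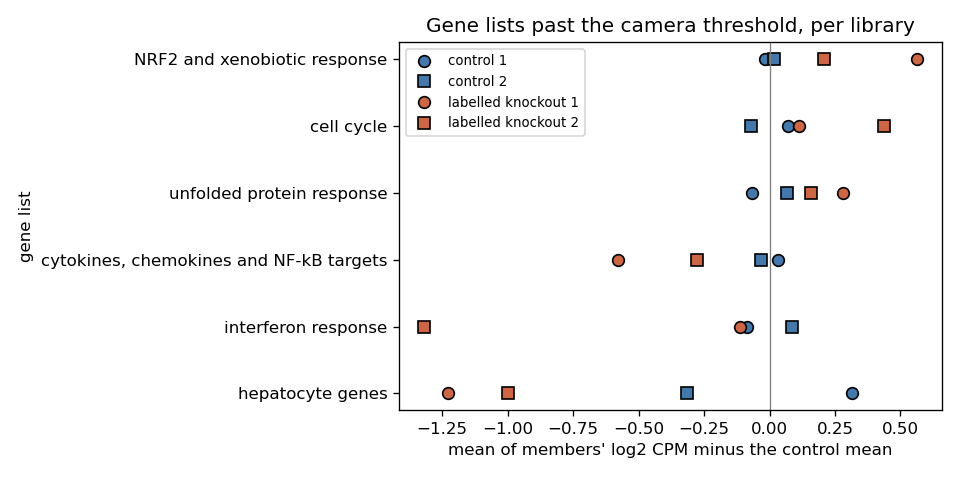
Each point is 1 library's mean log2 CPM over the members of a gene list, minus the mean of the 2 controls, for the 6 lists past the camera threshold. The interferon shift was -1.32 in Hhex knockout replicate 2 and -0.11 in replicate 1, and the cell cycle shift was 0.44 and 0.11.

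The other 30 of the 36 lists did not pass camera (limma). Among cell types that a ductal culture could hold, fibroblast and stellate markers had an adjusted p of 0.0635, with 13 of 16 fold changes negative and a mean log2 fold change of -0.51. Their mean log2 CPM, minus the control mean, was 0.30 and -0.30 in the controls. In the libraries labelled knockout it was -0.69 and -0.19, so the groups overlapped. Sparc stood at 12.5 and 4.01 CPM and Vim at 16.1 and 43.5 CPM. Adjusted over the list alone, Sparc fell and Vim rose. Macrophage and myeloid markers had the same camera adjusted p (limma) of 0.0635, with 10 of 12 fold changes negative and a mean log2 fold change of -0.61. Of them 0 were called over all genes or adjusted over the list alone. Here too the groups overlapped, with mean shifts of 0.42 and -0.42 in the controls and -0.85 and -0.11 in the others. The summed level was 170 and 151 CPM in the controls and 129 and 217 CPM in the libraries labelled knockout. Mesothelial markers had an adjusted p of 0.185, and Msln stood at 1798 and 3813 CPM and rose when adjusted over the list alone. The basal keratin gene Krt17 stood at 74.0 and 7.85 CPM and fell when adjusted over the list alone. In the Wnt list Wnt7b, at 248 and 442 CPM, and Ccnd1, the cyclin D1 gene, at 981 and 1810 CPM, rose when adjusted over the list alone, and Sp5, a Wnt target chosen after its values were seen, fell with a log2 fold change of -2.83. Of the 19 Wnt genes tested 11 had negative fold changes, and the camera adjusted p (limma) was 0.832. Genes described as HHEX targets had an adjusted p of 0.744, with Vegfa at 214 and 327 CPM.

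The sexes of the animals were not balanced. Xist, expressed from the inactive X, stood at 304 CPM in Hhex knockout replicate 2 and at 1.75, 0.892 and 0.750 CPM in the other 3 libraries. The Y-linked Ddx3y stood at 108, 158 and 202.4 CPM in those 3 and at 0.548 CPM in Hhex knockout replicate 2. Eif2s3y, Kdm5d and Uty, also Y-linked, lay between 51.95 and 161 CPM in those 3 libraries and at 0.548, 0.0968 and 0.194 CPM in Hhex knockout replicate 2. Globin genes, a check for blood, had at most 3 counts in any library. With the 1300 transcripts of X and Y genes left out of the tables, an alternative added after the data were seen, edgeR called 43 transcripts, 30 higher and 13 lower. Hhex knockout replicate 2 also held the larger interferon and cell cycle shifts, where sex cannot be told apart from other traits of that library. Without it, the mean log2 fold change went from -0.53 to -0.15 for the interferon list and from 0.28 to 0.085 for cell cycle. Those of Tfpi and Tm4sf1 were then -3.99 and -2.95.

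Some libraries of different groups were closer to each other than libraries of the same group. The SD of the log2 CPM difference was 0.621 between the controls and 0.712 between the libraries labelled knockout, but 0.555 between control replicate 2 and Hhex knockout replicate 1 and 0.572 between control replicate 1 and Hhex knockout replicate 2. The other pairs of different groups differed more, with 0.778 between both replicates 1 and 0.670 between both replicates 2. The first principal component (54.4% of variance) separated these mixed pairs, and the second (28.6%) separated the groups. Groups did not overlap for 36.2% of the symbols tested, where chance gives 33.3%. With 2 libraries per group an exact permutation test cannot give a two-sided p below 0.333.

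**Figure D4:**
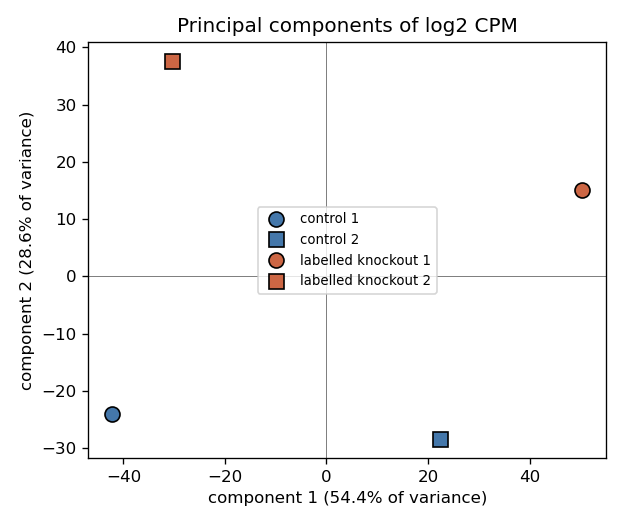
Principal components of log2 CPM, with component 1 (54.4% of variance) across and component 2 (28.6%) upward, 1 point per library. Control replicate 1 and Hhex knockout replicate 2 lie to the left, and both libraries labelled knockout lie above both controls.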

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

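Of the alternatives below, the single transcript per gene, the removal of X and Y genes and the covariate were chosen after seeing the data. The count of called transcripts (32, with 22 higher and 10 lower) stayed within 1.5 times with DESeq2's size factors, the legacy quasi-likelihood fit, limma-trend on log2(RPKM + 0.5) and without X and Y genes. It was lower with upper-quartile factors (5, with 0 higher and 5 lower), library totals (5, with 0 and 5), a filter of CPM of at least 1 in 2 libraries (4, with 0 and 4), limma-voom (16, with 11 and 5), glmTreat against a fold of 1.5 (6, with 2 and 4), an adjusted p of 0.01 (4, with 0 and 4), counts summed per symbol (14, with 11 and 3), 1 transcript per gene (2, with 0 and 2) and the share of reads in transcripts as a covariate (5, with 1 and 4). Without a low count filter the total of 25 and the 19 higher stayed within 1.5 times, and the lower count was 6. It was higher with DESeq2 (303, with 207 and 96), the edgeR exact test (264, with 168 and 96), robust quasi-likelihood (64, with 45 and 19), limma-trend on log2(RPKM + 0.1) (56, with 35 and 21) and on log2(RPKM + 1) with a mean RPKM of at least 1 (212, with 147 and 65). Leaving out each library gave 0 to 1911 calls, 0 to 1181 higher and 0 to 860 lower, with a lone library assumed to vary like the other group. The Hhex log2 fold change ran from 0.12 to 0.84 without each library in turn, and passed only without Hhex knockout replicate 1. The number of lists past the threshold was 0 with an estimated correlation and 0 with fry for a change in a set direction. With fry for change in either direction it was 2. With each library left out in turn, it moved beyond 1.5 times only without control replicate 2, where it was higher. With the CPM filter the hepatocyte list had under 5 members and no value. The SD between libraries of a group averaged 0.666 and was 0.732 with a prior count of 0.5. The log2 fold change of Ddx3y ran from -7.93 to 0.59 without each library in turn, and reversed without Hhex knockout replicate 2, the library with the fewest Y-linked counts. No called gene named by the rule changed direction in any alternative. The cause was not tested for the other shifts. With 2 libraries per group and the common coefficient of variation for every transcript, 26% of simulated 2-fold changes were recovered.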

Other observations

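The tests of sex, of natural killer or T cells, of shared reads and of exchanged libraries were chosen only after the results were seen, as was the 8-fold limit used for genes that stood apart in 1 library. Several genes missed the edgeR threshold narrowly. Scnn1g, a subunit gene of the epithelial sodium channel, stood at 1.02 and 0.811 CPM in the controls and at 8.22 and 5.64 CPM in the libraries labelled knockout (edgeR adjusted p = 0.0512), and Scnn1a, another subunit gene, at 15.05, 14.6, 36.2 and 31.7 CPM (edgeR adjusted p = 0.0539). The double-stranded RNA receptor gene Tlr3 stood at 73.7 and 83.4 CPM in the controls and at 204 and 317 CPM in the others, and the apical membrane gene Mal at 178, 239, 658 and 1041 CPM. The keratin gene Krt23 stood at 18.5 and 61.8 CPM in the controls and at 1.42 and 2.52 CPM in the others (edgeR adjusted p = 0.067). These genes were chosen after their values were seen.

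Some genes stood at least 8-fold lower or higher in 1 library than in each of the other 3. In Hhex knockout replicate 1, Plac8 stood at 8.41 CPM against 84.4, 95.1 and 143 CPM, Aldh1l1 at 1.71 CPM against 36.6, 17.4 and 57.9 CPM, and Anxa13 at 1.10 CPM against 15.1, 16.1 and 24.8 CPM. In Hhex knockout replicate 2, the water channel gene Aqp5 stood at 57.2 CPM against 1.42, 2.59 and 0.750 CPM, and the matricellular gene Wisp2 at 29.4 CPM against 2.44, 2.27 and 0.750 CPM.

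The Hhex count was not lower in the libraries labelled knockout. An exchange of a control and a knockout library was tested through the other 2 splits of the 4 libraries into pairs. Both called 0 transcripts in edgeR against 32 for the labels, and by this count, the measure set for the test, the result went against an exchange. However, the split of control replicate 1 and Hhex knockout replicate 2 from the others had 2534 transcripts with an unadjusted p under 0.05 against 1573. Hhex stood at 24.8 and 39.0 CPM in that pair and at 17.7 and 23.6 CPM in the others. An exchange therefore stays open. If exons 2 and 3 are the deleted ones, they hold 12.8% of the 1802 bases of the GENCODE transcript, and a full deletion could leave most of the count in place. The labels do not say which exons were deleted, so this cannot be told apart from incomplete recombination, which was not tested.

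The 6 called Klra genes were higher in both libraries labelled knockout. Natural killer or T cells are argued against, since the summed CPM of 10 of their genes was 0.695 times that of the controls, while Klra4 rose 3.70-fold. The called Klra genes kept their ratio to Klra4 across libraries to within 1.17-fold, which goes with 1 signal counted in several near-identical rows. They were picked by their calls in this same comparison, which favours like ratios, so the ratios alone cannot decide this. Klra3, Klra8, Klra9, Klra14 and Klra21, however, lay above both controls in CPM in Hhex knockout replicate 1 and below both in replicate 2, with Klra8 at 956 and 7 counts there and 95 and 146 in the controls. A genome segment of another strain may underlie such a difference, but of 11 other genes at least 8-fold apart in 1 library none had such a neighbour within 5 genes (one-sided permutation p = 1), and random draws also gave a median of 0, so that test had no reach and the explanation stays open, as does a true effect of the genotype.

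Control replicate 1 and Hhex knockout replicate 2 stood apart from the other 2 libraries on the first principal component. Sex is argued against, since the male control replicate 1 lay 11.8 units from the female library and 64.5 units from the nearest other male. Reads from outside mature transcripts stay open as a candidate explanation. Olfactory, vomeronasal and trace amine receptor genes, silent in ducts, had 1.54 times the mean CPM in this pair. The excess lay mainly in control replicate 1, at 301 CPM. Hhex knockout replicate 2 stood at 185.6 CPM, control replicate 2 at 179.9 CPM and Hhex knockout replicate 1 at 135.4 CPM. These CPM were taken over the unscaled total of the transcripts that stand for a gene. The ratio on the TMM-scaled library was not tested. The intervals of Hhex knockout replicate 2 (180.0 to 191.3) and control replicate 2 (173.9 to 186.1) overlapped. Counts in transcripts were an estimated 48.6% and 55.2% of the library total in this pair and 57.8% and 61.8% in the others.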
